A study of Mus musculus with 8 samples.

How the data were processed

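Genomic DNA of 8 renal cell carcinomas from ferric nitrilotriacetate-treated male A/J mice was hybridised to Agilent mouse genome CGH 180K arrays. Each array compared 1 tumour, labelled with Cy5, with normal kidney DNA of A/J mice, labelled with Cy3. No array had the dyes swapped, so a dye effect of a probe does not cancel in any mean given here.

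The authors scanned the arrays and extracted the spots with Agilent Feature Extraction 10.7, per the submitters' processing notes, and version 10.7.1.1 is given per the file headers. The deposited spot intensity values used here are the processed signals, which the scanner software had background-subtracted, spatially and multiplicatively detrended, and put through a linear dye normalization, per the file headers. Low signals had been replaced by values from the software's error model, per the file headers. The deposited scanner files also hold a log10 ratio of Cy5 over Cy3, which equals the ratio of the processed signals except at 21 to 111 spots per array. The deposited series table holds log2 values. Set against the scanner files by feature number, its columns equalled that log10 ratio turned to log2 on each array, with no difference above 5.00066e-07 over 174303 matched features. Scale, direction and centring of the series table are therefore known, and its column medians for tumours 1 to 8 were 0.033, 0.022, 0.014, -0.011, 0.0036, 0.0026, -0.00058 and 0.0054. Probe positions are those of the mouse assembly mm9, per the file headers.

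From the 174305 features per array that were not controls, 137 to 245 outlier spots were left out of each array and none was saturated. The log2 ratio of tumour over normal kidney was taken from the processed signals, spots of 1 probe were averaged, and each array was centred on the median of its autosomal probes, with no loess and no quantile step. This left 170305 probes with a position, with a median spacing of 10.9 kb. The gene column named 66.9% of the probes. Of 21138 names, 15214 were matched to a current symbol through a RefSeq gene table of assembly GRCm38.p6 and 5924 were not. That table was used for names and for the order of neighbouring genes only. A gene's value is the mean of its probes, and its position runs from the first to the last probe that carries its name. Genes without a probe named for them were described by the probes between their named neighbours.

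Segments were found on each chromosome of each array by penalised least squares (optimal partition), with at least 5 probes per segment and a penalty of 3 times the logarithm of the number of probes times the noise variance. A segment with a mean of 0.25 or above was called a gain and one of -0.25 or below a loss. A gene was called by the same limits on the median of the segment means at its probes. Segments beyond 1 on the log2 scale in either direction were called high-level gains or deep losses, and a chromosome was called lost or gained as a whole where 80% of its probes lay in such segments. Tumour purity is not given in the sources used here, so no copy numbers were derived. Recurrence was counted in 2538 bins of 1 Mb on the autosomes and chromosome X, with family-wise p-values from 10000 rotations of each tumour's profile around the genome, a one-sided permutation test. Chromosome means, shares of the genome and antigen receptor loci were tested against 0 by exact sign-flip permutation tests, whose smallest possible p is 0.0078125 for 8 tumours. Gene means were tested against 0 with limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. A ratio against 0 leaves out the spread of the normal kidney DNA, because it is the only control. Segmentation, rotations and exact tests were run in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and numba 0.67.0.

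The 7 gene lists were fixed before the data were examined, as were the design, most of the other processing choices tried and the rule for named genes. They hold renal carcinoma genes, cell cycle and p53 genes, growth factor and RAS pathway oncogenes, iron handling genes, ferroptosis and NRF2 pathway genes, oxidative DNA damage repair genes, and large fragile-site genes. Losses of list members were compared with 10000 rotations of each tumour's profile along the ordered genes. That test moves each tumour separately and so removes the places where tumours share a loss. Of 200 random lists drawn on the profiles as measured, 53 had a p under 0.05, against 3 of 200 on profiles shifted at random, so the planned p-values are too small for a comparison of a list with other genes. A comparison with 10000 random lists of the same size was therefore added after the data were seen. The rule named list members past the limma threshold over all genes and at most 4 others per list by size of the mean, list members or at most 2 genes in the 3 most recurrent gained and lost regions and in each high-level segment, and Cdkn2a, Cdkn2b, Met and Myc in every tumour. Some genes that the rule names are counted with their lists and are not reported here by name.

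The procedures were tested on simulated data. The segmentation reached the cost of a full search in 50 of 50 short series. Over 8 simulated arrays with implanted segments and independent normal noise, it called 0 segments that lay wholly outside the implanted ones. It recovered 64 of 64 implanted segments of 50 probes at a log2 ratio of 0.4 and 15 of 64 of 10 probes at 0.4. Of those of 5 probes it recovered 39 of 64 at 0.8 and 1 of 64 at 0.4. Probes in many gained segments of the measured arrays spread more widely than the simulated noise, so the count of 0 does not carry over to them. Rotations gave a family-wise p under 0.05 in 6 of 200 sets of shifted profiles and in 200 of 200 sets with a block placed in 7 tumours. With 200 of 15212 genes changed by 0.2, limma recovered 100 of them and called 6 of 15012 unchanged genes, and with a change of 0.4 it recovered 151 and called 13. The simulated genes varied independently, without shared segments or probe offsets that recur on every array. These counts of false calls therefore do not carry over to the measured genes.

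The other processing choices tried covered the background correction (normexp with an offset of 50), the deposited log ratios, the centring, the filter on dim probes, outlier spots, a loess on GC content, the slide, each tumour left out, and the thresholds, penalties, bin sizes and tests. Leaving out probes dim in normal kidney DNA (under 0.1 of the array's median signal), mode centring together with a test against 0.1, and the slide as a random block were added after the data were seen. The arrays came from 2 slides of 4, with tumours 1 to 4 on slide 1 and tumours 5 to 8 on slide 2. Between 99.5% and 99.7% of probes were above background in both channels. Replicate spots varied more in the tumour channel on slide 1 (coefficient of variation 18.0% to 24.6%) than on slide 2 (7.70% to 10.5%), and the noise between neighbouring probes ranged from 0.134 to 0.265 on the log2 scale. The number of arrays, 8, limits the precision of every mean.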

Results

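The study profiled DNA copy number in renal cell carcinomas that arose in male A/J mice given ferric nitrilotriacetate, an iron chelate that injures the proximal tubules of the kidney through iron-catalysed oxidation. The mice were injected into the peritoneum 5 times a week for 12 weeks, at 5 mg of iron per kg for 2 weeks and then at 7 mg per kg for 10 weeks. The protocol was started with 58 mice, and 18 developed a renal cell carcinoma. The deposited arrays cover 8 tumours, whereas the design text of the series speaks of 4 samples. Array comparative genomic hybridisation reads the ratio of tumour DNA to normal kidney DNA at each probe. A log2 ratio of 0 means no difference from the centre of the array, and admixed normal cells pull every ratio towards 0. Median processed signals were 1085 to 1135 in the normal kidney channel and 1060 to 1125 in the tumour channel. The labels give each tumour its own identifier and do not say whether every tumour came from a different mouse, so the p-values measure the spread between these tumours. All 8 tumours form 1 group, and every comparison is with normal kidney DNA of the same strain.

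The first comparison asked how much of the genome was lost or gained in the tumours. Loss of DNA dominated every profile. Segments called lost covered 12.6% ± 4.83 of the autosomal and X probes (SD, n = 8), and segments called gained covered 0.129% ± 0.0729 (SD, n = 8). The lost share was lowest in tumour 4, at 2.88%, and highest in tumour 8, at 17.6%, with a median of 13.7%. In tumour 4 chromosome 11 averaged 0.19, a rise below the call limit that these shares leave out. Tumours 1, 2, 3, 5, 6 and 7 had lost shares of 15.03%, 11.9%, 13.2%, 14.2%, 17.1% and 8.85%. The share gained minus the share lost averaged -12.5 percentage points ± 4.81 (SD, n = 8), with more lost than gained in 8 of 8 tumours, and its exact sign-flip p of 0.0078125 is the smallest that 8 tumours can give. The 113 lost segments outside chromosome Y were mostly long, 97 of them over 1 Mb, while 2 of the 149 gained segments exceeded 1 Mb. In 92 of the gained segments most probes were dim in normal kidney DNA, that is, under 0.1 of the array's median signal, and without such probes, a filter chosen after the data were seen, the gained share was 0.0258%.

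**Figure D1:**
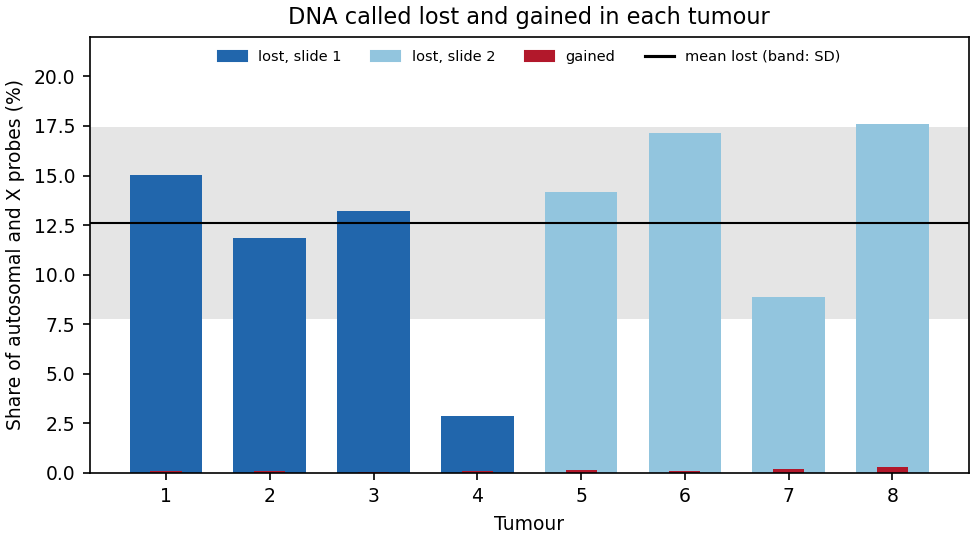
The share of autosomal and X probes in lost and gained segments, in percent, is drawn as bars for each of the 8 tumours, with the mean lost share of 12.6% as a line and its SD as a band. Lost shares run from 2.88% in tumour 4 to 17.6% in tumour 8, and gained shares stay at or below 0.279%.

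With the call limit of 0.25, whole chromosomes were called lost but not gained. At 80% of the probes, 14 whole-chromosome losses were called among the autosomes and chromosome X, 5 of chromosome 12, 3 each of chromosomes 13 and 14, 2 of chromosome 4 and 1 of chromosome 1, against 0 whole-chromosome gains. The absence of such gains depends on the call limit, since a limit of 0.15 gave 1 whole-chromosome gain. Chromosome 11 averaged 0.19 in tumour 4, below the limit of 0.25, against 0.011 to 0.082 in the other tumours. Chromosome 4, which carries Cdkn2a and many other genes known as tumour suppressors, had the lowest mean of the 21 chromosomes. Its mean log2 ratio was -0.31 ± 0.23 (SD, n = 8), a ratio of 0.808 to normal kidney, and it was lower in 8 of 8 tumours. Chromosomes 12, 13 and 14 averaged -0.25 ± 0.27, -0.21 ± 0.28 and -0.20 ± 0.26 (SD, n = 8). Chromosome Y averaged -0.25 ± 0.55 (SD, n = 8), with -1.45 in tumour 8, and was also called lost over its whole length in tumours 2, 5 and 8.

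Chromosome 4 was lower in the exact sign-flip test after Benjamini-Hochberg adjustment over the 21 chromosomes (adjusted p = 0.0182), and chromosomes 12, 13, 14 and Y did not pass it (exact test, adjusted p = 0.104, 0.202, 0.191 and 0.387). Another 9 chromosomes were higher in that test by 0.034 to 0.055, while the mode of an array's bins lay 0.014 to 0.068 above the median used for centring. With each array centred on the mode of its bins, 0 chromosomes passed in either direction, although 9 had an unadjusted exact p under 0.05, and chromosome 4 averaged -0.35 (exact test, adjusted p = 0.0547). Unadjusted, chromosome 4 had the smallest possible exact p, 0.0078125, with either centring. Its adjusted p therefore follows from how many other chromosomes also reached that p, so passing or failing says nothing more about chromosome 4 itself. Within slides, chromosome 4 averaged -0.50 ± 0.16 in tumours 1 to 4 and -0.12 ± 0.061 in tumours 5 to 8 (SD, n = 4 each), where an exact test of 4 tumours cannot go below 0.125.

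**Figure D2:**
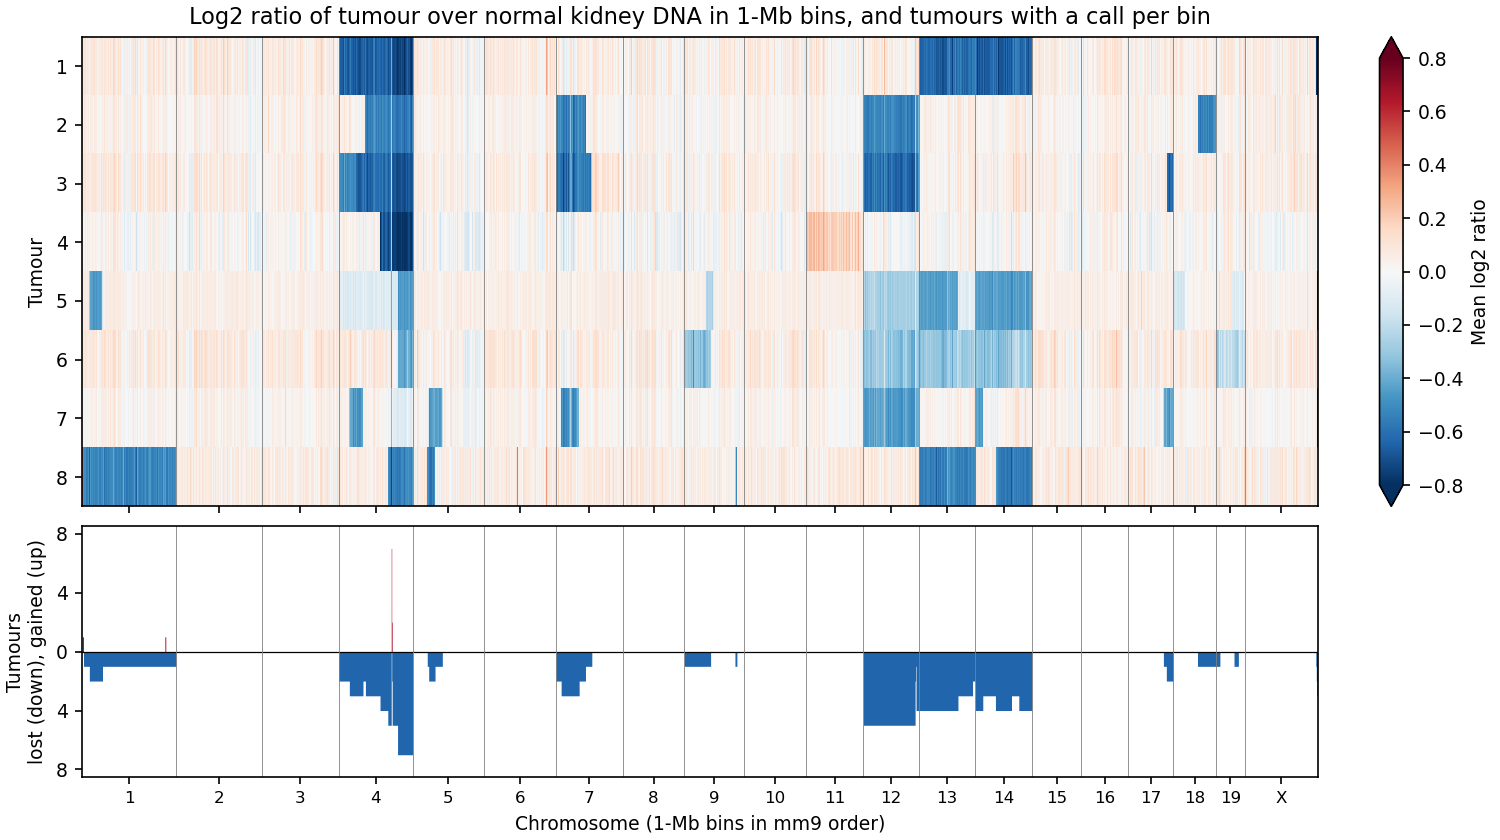
The upper panel colours the mean log2 ratio of tumour over normal kidney DNA in 1-Mb bins for tumours 1 to 8 along the autosomes and chromosome X, and the lower panel counts the tumours with a lost or gained call in each bin. Blue blocks of loss recur on chromosomes 4, 12, 13 and 14, and the tallest column of losses, at 7 tumours, lies at the distal end of chromosome 4.

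The recurrence of losses was then mapped along the chromosomes. The distal part of chromosome 4, from position 125035957 to 155629081 (mm9), was lost in 7 of 8 tumours, all except tumour 7, whose loss on chromosome 4 lay elsewhere, from 25232469 to 53474828. This distal region holds Sdhb, a subunit of succinate dehydrogenase, at -0.70 ± 0.32 (SD, n = 8), Arid1a, a subunit of the SWI/SNF chromatin remodelling complex, at -0.47 ± 0.23 (SD, n = 8), and Mtor, the kinase that couples growth to nutrients, at -0.37 ± 0.17 (SD, n = 8). All 3 genes were below 0 in 8 of 8 tumours and were lower in limma (adjusted p = 0.00151, 0.00204 and 0.00188). In tumour 7, where none of them was called lost, Mtor and Arid1a were close to 0 (-0.0033 and -0.0094). Sdhb, on 2 probes, was at -0.15 there. With segment means Sdhb, Arid1a and Mtor were nearly equal, at -0.535, -0.536 and -0.535. Of the 382 genes tested in the region, 376 were lower in limma. The region was chosen by its losses in these same tumours and its genes share segments, so the gene tests add no separate support. The region's border was close to identical in tumours 5 and 6, whose losses began at 125112975 and 124895440, while tumour 3 had lost the whole chromosome and tumour 4 began at 88917436, beside Cdkn2a.

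**Figure D3:**
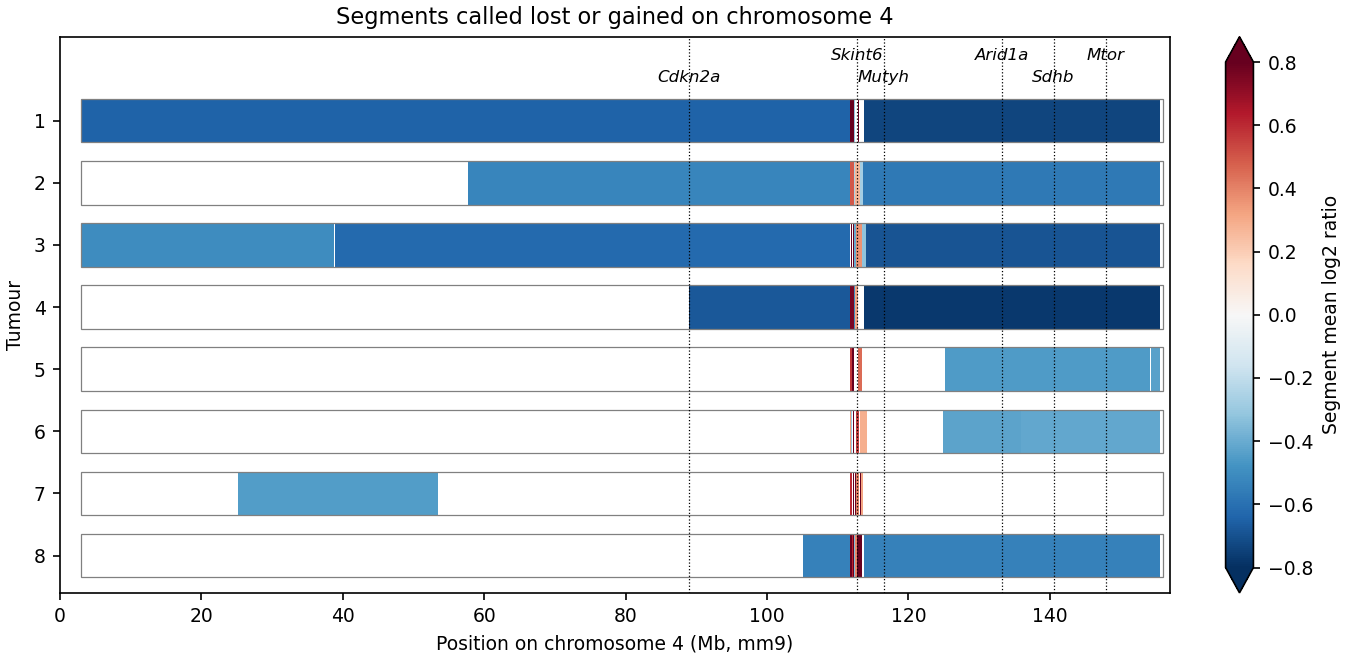
Segments called lost or gained on chromosome 4 are drawn for tumours 1 to 8 against position in Mb (mm9), coloured by segment mean log2 ratio, with dotted lines at Cdkn2a, Skint6, Mutyh, Arid1a, Sdhb and Mtor. Every tumour except tumour 7 has a loss that covers Arid1a, Sdhb and Mtor.

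The 31 bins of the distal region were the only lost bins past the family-wise threshold (permutation p = 0.0005, n = 8 tumours). Lost bins shared by 5 tumours, such as chromosome 12 from 25135356 to 114988623 (tumours 2, 3, 5, 6 and 7), did not pass it (permutation p = 0.1626, n = 8), nor did the losses of chromosomes 13 and 14 in tumours 1, 5, 6 and 8 (permutation p = 0.7508, n = 8). Chromosome 12 contains Hs1bp3 at -0.53 ± 0.29 and Sf3b6, a splicing factor, at -0.52 ± 0.32 (SD, n = 8), both lower in limma (adjusted p = 0.00305 and 0.00459). With segment means both were at -0.25 (limma adjusted p = 0.0464). Hs1bp3 was also at -0.54 and -0.47 in tumours 1 and 4, which have no loss of this chromosome, and Sf3b6 rests on 1 probe. The chromosome also holds Hif1a, the oxygen-regulated transcription factor, at -0.16 ± 0.28 (SD, n = 8), which did not pass. Within slide 1 the losses reached the threshold in 65 bins, and within slide 2, where the most frequent loss was in 3 tumours, they reached it in 0 bins (permutation p = 0.742, n = 4).

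Among the 1-Mb bins, those gained in more than 1 tumour lay in 1 stretch of chromosome 4. The bin at 112006991 to 112975272 on chromosome 4, inside the Skint cluster of genes related to the selection of epidermal T cells, was called gained in 7 tumours (permutation p = 0.0001, the smallest that 10000 rotations can give, n = 8). Skint6 averaged 0.41 ± 0.17, Skint9 0.61 ± 0.42, Skint4 0.63 ± 0.33 and Skint3 0.66 ± 0.47 (SD, n = 8), all 4 higher in limma (adjusted p = 0.00142, 0.00731, 0.00239 and 0.00872). In this bin 82.7% of the probes were dim in normal kidney DNA, and without dim probes the most frequent gain was in 1 tumour and 0 bins passed. Gained segments narrower than a bin also recurred, for example on chromosome 16 at or beside Csta2 in tumours 1, 2, 4, 5, 6, 7 and 8. A neighbouring bin, from 113001582 to 113993176, was gained in tumours 6 and 7 (permutation p = 0.029, n = 8), with 54.8% dim probes. The next gained region by recurrence, chromosome 1 from 3017293 to 5971878 in tumour 8, holds Tcea1, a transcription elongation factor, at 0.13 ± 0.20, and Oprk1, the kappa opioid receptor, at 0.14 ± 0.24 (SD, n = 8), and neither passed in limma.

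Deep losses were described tumour by tumour. Tumour 4 had a deep loss at Cdkn2a, which encodes the p16 and p19Arf tumour suppressor proteins, on chromosome 4 from 88917436 to 89076517, with a mean of -2.50 ± 0.090 (SE, 10 probes). Cdkn2a itself was called lost in tumours 1, 2, 3 and 4 and averaged -0.68 ± 0.86 (SD, n = 8), and it did not pass in limma (adjusted p = 0.0687), although it did without tumour 4 (adjusted p = 0.0456). Tumour 1 had a deep loss within Fhit, a very large gene at a chromosomal fragile site, on chromosome 14 from 11122068 to 11225834, at -2.04 ± 0.082 (SE, 11 probes). The distal end of chromosome X, where Frmpd4, Arhgap6 and Mid1 lie, was deeply lost in 3 tumours, from 163399461 in tumour 1 (-1.97 ± 0.027, SE, 261 probes), from 164449267 in tumour 5 (-1.21 ± 0.016, SE, 168 probes) and from 164993844 in tumour 7 (-1.08 ± 0.018, SE, 115 probes), in each case to the last probe at 166421899. Tumour 8 had 2 deep losses on chromosome Y, at -1.56 ± 0.040 (SE, 96 probes) and -1.12 ± 0.17 (SE, 18 probes), and the deeper of them covers Uty and Usp9y. SE here is between probes of 1 array, and these calls in single tumours have no test.

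**Figure D4:**
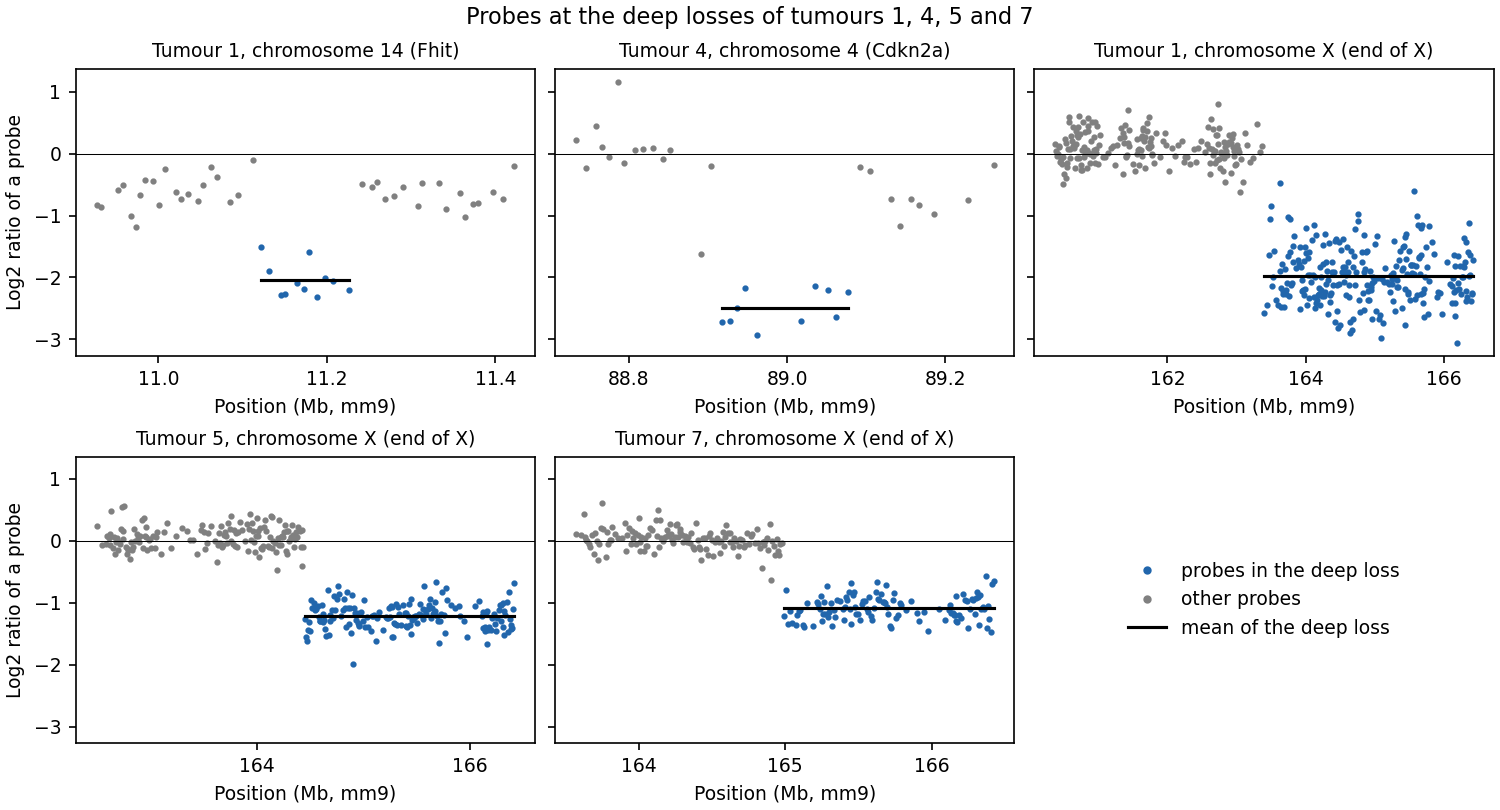
Log2 ratios of single probes are plotted against position in Mb (mm9) around the deep losses of tumours 1, 4, 5 and 7, with the probes of the deep loss in blue, other probes in grey and the mean of the deep loss as a line. The mean levels are -2.04 in Fhit, -2.50 at Cdkn2a, and -1.97, -1.21 and -1.08 at the end of chromosome X.

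High-level gains numbered 27 segments, among them segments at Csta2, a cystatin of the stefin family, which averaged 0.65 ± 0.25, and at Apol10a and Apol11a, which averaged 0.70 ± 0.56 and 0.78 ± 0.79 (SD, n = 8), all 3 higher in limma (adjusted p = 0.00123, 0.0132 and 0.0334), Apol11a not in every fit with 1 tumour left out (adjusted p up to 0.0719) and not with the slide as a random block (adjusted p = 0.0638 with an estimated correlation). Segments of this kind also lay at G6pd2, which averaged 0.24 ± 0.15 (SD, n = 8) and was higher in limma (adjusted p = 0.00541), and at Prkd1, Trim12a and Trim12c, which were not. Prkd1 changes sign when tumour 2 or tumour 3 is left out (0.0059 and 0.0087), and Trim12c when tumour 8 is (-0.0060). With segment means Csta2 was at 0.61, Apol10a and Apol11a both at 0.26 and G6pd2 at 0.18, and none of the 4 passed in limma (adjusted p = 0.0520, 0.272, 0.272 and 0.224). Without dim probes 0 high-level gains were called. Met, the receptor of hepatocyte growth factor, averaged 0.078 ± 0.044 (SD, n = 8), was higher in limma (adjusted p = 0.0239) and was in no called segment in any tumour. With mode centring its limma adjusted p was 0.246. Myc, for which no probe is named, was read from 51 probes between A1bg and Pvt1 on chromosome 15, at -0.0027 ± 0.048 (SD, n = 8; exact sign-flip p = 0.867), with 0 tumours lost or gained. Cdkn2b, read from 36 probes between Cdkn2a and Zfp352, was at -0.33 ± 0.41 (SD, n = 8; exact sign-flip p = 0.109) and was called lost in tumours 1, 2, 3 and 4, with -0.96 in tumour 4, whose deep loss runs past Cdkn2a into the first part of this interval. That deep loss ends at 89076517 and the interval at 89889640, so -0.96 averages probes inside and beyond the deep loss. It is not the level at Cdkn2b itself, which may lie within the deep loss.

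Gene by gene, many mean log2 ratios differed from 0 in limma, which a probe offset that recurs on every array can also produce. Of 15214 genes, 2704 were lower and 3347 were higher in limma with Benjamini-Hochberg adjustment. Chromosome 4 held 603 of the lower genes among 939 tested, and on chromosome 12 the lower genes made up 50.1% of those tested. Among the genes past the threshold, 4362 were called gained or lost in no tumour, 3256 of them higher and 1106 lower. Neighbouring genes share segments and are not independent, and 4605 genes rest on 1 probe. The split depends on the centring, with 1733 higher and 4096 lower genes under mode centring. It was 1945 higher and 1750 lower with normexp background correction, and 520 higher and 825 lower in limma's test against a log2 ratio of 0.1. With the slide as a random block 2716 were higher and 2032 lower, while limma called 2615 genes higher and 2463 lower within slide 1 and 0 genes within slide 2, there with 2179 higher and 1890 lower at an unadjusted p under 0.05.

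Among renal carcinoma genes, Sdhb, Mtor and Arid1a on chromosome 4 were each called lost in 7 tumours. Of 21 measured members, 4 were lower in limma, Sdhb, Mtor, Arid1a and Tfeb, and 6 were higher, among them Kdm6a, Nf2, Met, Tfe3 and Mitf, both over all genes tested and adjusted over the list alone. Tfeb, a transcription factor of lysosome biogenesis, averaged -0.13 ± 0.11, and Nf2, the gene of merlin, 0.15 ± 0.088 (SD, n = 8). Tfeb, Met, Tfe3 and Mitf did not pass in every fit with 1 tumour left out (limma adjusted p up to 0.0690, 0.0592, 0.0662 and 0.0590), and Tfe3 did not with the slide as a random block (limma adjusted p = 0.0512 with an estimated correlation). The counts of higher and lower members were 0 and 7 with mode centring, 2 and 3 with normexp, 6 and 4 with segment means, where Tfeb was at 0.0021 (limma adjusted p = 0.944), and 0 and 3 in the test against 0.1. None of the 6 higher members passed with mode centring, and no called segment covered Nf2 or Met in any tumour. Members had 33 losses in 168 pairs of gene and tumour, against 21.0 in the rotations (permutation adjusted p = 0.0133, n = 8), and 0 gains. Against random lists of the same size the adjusted p was 0.537, so the list did not stand apart from other genes. The von Hippel-Lindau gene Vhl had 1 probe, at -0.015 ± 0.10 (SD, n = 8), and was called lost in no tumour. Pbrm1 was called lost in tumours 1, 5 and 6 and Setd2 in tumour 8, and neither passed in limma.

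Cell cycle and p53 genes lay on both sides of 0. Of 16 measured members 4 were lower and 2 were higher over all genes, and the same numbers passed when adjusted over the list alone. Cdkn1a, which encodes the cell cycle inhibitor p21, was at -0.49 ± 0.29, Ccne1, cyclin E1, at -0.34 ± 0.31, E2f3 at -0.31 ± 0.32 and Ccnd2, cyclin D2, at -0.23 ± 0.20 (SD, n = 8). Cdkn1a and Ccne1 rest on 1 probe each, and Cdkn1a was called lost in no tumour. With segment means these 4 did not pass in limma, Cdkn1a at -0.033, Ccne1 at -0.17, E2f3 at -0.23 and Ccnd2 at 0.014 (adjusted p = 0.331, 0.131, 0.0816 and 0.402), nor did Trp53 at 0.046 (adjusted p = 0.101). Counts of higher and lower members were 1 and 5 with mode centring, 0 and 1 with normexp, 2 and 1 with segment means, and 0 and 1 in the test against 0.1. Trp53, the p53 gene, was at 0.22 ± 0.13 and Cdk6 at 0.065 ± 0.038 (SD, n = 8), higher and also in no called segment. Ccne1, E2f3, Ccnd2 and Cdk6 did not pass in every fit with 1 tumour left out (limma adjusted p up to 0.0546, 0.0843, 0.0554 and 0.101), and E2f3 and Cdk6 did not with the slide as a random block (limma adjusted p = 0.0721 and 0.0653 with an estimated correlation). Rb1, the retinoblastoma gene, was called lost in tumours 1, 5, 6 and 8 and did not pass. Members had 22 losses in 128 pairs against 16.0 in the rotations (permutation adjusted p = 0.0884, n = 8).

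Oncogenes of the growth factor and RAS pathways showed no called gains in any tumour. Of 16 measured members 5 were higher, among them Pik3ca at 0.18 ± 0.036, Egfr at 0.11 ± 0.089 and Braf at 0.086 ± 0.063 (SD, n = 8), and 0 were lower. The counts were the same adjusted over the list alone, while 2 were higher and 3 lower with mode centring, 4 and 0 with normexp, 10 and 1 with segment means, and 1 and 0 in the test against 0.1. With segment means the levels were smaller, Pik3ca at 0.054, Egfr at 0.089 and Braf at 0.050 (limma adjusted p = 0.00131, 0.0107 and 0.00132). Egfr and Braf did not pass in every fit with 1 tumour left out (limma adjusted p up to 0.0548 and 0.0734), and Braf did not with the slide as a random block (limma adjusted p = 0.0580 with an estimated correlation). Akt1 was called lost in tumours 2, 3, 5, 6 and 7 and Akt2 in tumours 2, 3 and 7, and neither passed in limma. The list had 10 losses in 128 pairs against 16.0 in the rotations (permutation adjusted p = 0.258, n = 8).

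Genes of iron handling and of ferroptosis, the iron-dependent form of cell death, were examined because the carcinogen delivers iron. Of 12 measured iron genes 3 were higher and 1 was lower, both over all genes and adjusted over the list alone. Slc11a2, the divalent metal transporter, was at 0.084 ± 0.065, Cp, ceruloplasmin, at 0.11 ± 0.072, Lcn2, lipocalin 2, at 0.24 ± 0.25 and Steap3, a ferrireductase, at -0.21 ± 0.16 (SD, n = 8). Counts of higher and lower iron genes were 0 and 3 with mode centring, 1 and 1 with normexp, 3 and 0 with segment means, and 0 and 0 in the test against 0.1. With segment means Slc11a2 was at -0.014, Lcn2 at -0.018 and Steap3 at -0.021 (limma adjusted p = 0.582, 0.454 and 0.818). Aco1, which encodes iron regulatory protein 1, was called lost in tumours 1, 3 and 7 and did not pass. Of 18 measured ferroptosis and NRF2 pathway genes 4 were higher and 2 lower, with the same counts adjusted over the list alone. Slc7a11, the cystine transporter, was at 0.14 ± 0.044, Acsl4, a lipid-activating enzyme, at 0.16 ± 0.047, Nfe2l2, which encodes NRF2, at 0.15 ± 0.075, Sod1, superoxide dismutase, at 0.41 ± 0.16 on 1 probe, Tfam at -0.13 ± 0.062 and Fancd2 at -0.093 ± 0.076 (SD, n = 8). Counts of higher and lower genes were 4 and 7 with mode centring, 4 and 1 with normexp, 9 and 1 with segment means, and 1 and 0 in the test against 0.1. With segment means Sod1 was at 0.012, Fancd2 at 0.014 and Tfam at 0.035 (limma adjusted p = 0.402, 0.402 and 0.0211). None of the 6 named genes was called gained or lost in any tumour, although a gained segment of 5 probes in tumour 7 overlaps Slc7a11, and Prdx1, a peroxiredoxin, was called lost in tumours 1, 2, 3, 4 and 8 without passing. Slc11a2, Lcn2 and Fancd2 did not pass in every fit with 1 tumour left out (limma adjusted p up to 0.0728, 0.0869 and 0.0844), nor with the slide as a random block (limma adjusted p = 0.0643, 0.0753 and 0.0581 with an estimated correlation). Losses numbered 12 in 96 pairs for iron genes against 12.0 in the rotations (permutation adjusted p = 1, n = 8) and 7 in 144 pairs for ferroptosis genes against 18.1 (permutation adjusted p = 0.0591, n = 8).

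Among repair genes of oxidative DNA damage, Mutyh, the glycosylase that removes adenine opposite oxidised guanine, stood lowest at -0.54 ± 0.44 (SD, n = 8; limma adjusted p = 0.0153) and was called lost in tumours 1, 2, 3, 4 and 8. Of 15 measured members 1 was lower and 6 were higher over all genes, and 2 and 6 adjusted over the list alone. The higher genes included Nthl1 at 0.22 ± 0.076, Lig3 at 0.19 ± 0.12, Brca2 at 0.15 ± 0.066, Polb at 0.14 ± 0.070 and Neil3 at 0.10 ± 0.074 (SD, n = 8). Counts of higher and lower members were 4 and 2 with mode centring, 4 and 1 with normexp, 2 and 1 with segment means, and 1 and 0 in the test against 0.1. With segment means Nthl1 was at 0.034, Lig3 at 0.046 and Brca2 at -0.015 (limma adjusted p = 0.122, 0.101 and 0.486). Neil3 did not pass in every fit with 1 tumour left out (limma adjusted p up to 0.0591). Xrcc1, the scaffold of base excision repair, at -0.23 ± 0.34 (SD, n = 8) did not pass over all genes. The list had 17 losses in 120 pairs against 15.04 in the rotations (permutation adjusted p = 0.755, n = 8).

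Very large genes at fragile sites carry many probes each. Of 15 measured members 7 were higher and 1 was lower, with the same counts adjusted over the list alone. Counts of higher and lower members were 0 and 2 with mode centring, 2 and 0 with normexp, 9 and 0 with segment means, where Immp2l was at -0.24 (limma adjusted p = 0.0509), and 0 and 0 in the test against 0.1. The higher genes included Lrp1b at 0.11 ± 0.053, Dlg2 at 0.10 ± 0.035, Dmd at 0.084 ± 0.041, Csmd1 at 0.078 ± 0.029, Macrod2 at 0.069 ± 0.030 and Magi2 at 0.054 ± 0.015 (SD, n = 8). Immp2l on chromosome 12 was lower at -0.26 ± 0.26 (SD, n = 8; limma adjusted p = 0.0351) and was called lost in the 5 tumours with a loss of that chromosome. Macrod2, Magi2 and Immp2l did not pass in every fit with 1 tumour left out (limma adjusted p up to 0.0694, 0.0939 and 0.0791), and Magi2 and Immp2l did not with the slide as a random block (limma adjusted p = 0.0766 and 0.0688 with an estimated correlation). Fhit averaged -0.21 ± 0.30 and Ptprd -0.12 ± 0.30 (SD, n = 8), and neither passed. The list had 14 losses in 120 pairs against 15.04 in the rotations (permutation adjusted p = 0.974, n = 8).

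Rearranged antigen receptor loci were read as a marker of lymphocyte DNA, since lymphocytes lack part of these loci. None of the 5 loci passed in the exact sign-flip test against 0 after adjustment (adjusted p of at least 0.156), with means from -0.17 for Tcrg to 0.044 for Igk. Set against the flanking 2 Mb, the immunoglobulin heavy chain locus Igh lay 0.22 ± 0.047 above its flanks (SD, n = 8; exact adjusted p = 0.0195) in 8 of 8 tumours, the Tcra/Tcrd locus 0.092 ± 0.049 (SD, n = 8; exact adjusted p = 0.0195) and the Tcrg locus 0.049 ± 0.040 (SD, n = 8; exact adjusted p = 0.026). Igk and Tcrb differed from their flanks by -0.013 ± 0.082 and -0.010 ± 0.037 (SD, n = 8; exact adjusted p = 0.797 and 0.566). Without dim probes Igh stood 0.075 ± 0.041 above its flanks (SD, n = 8; exact adjusted p = 0.0391), and Tcra/Tcrd 0.018 ± 0.048 (SD, n = 8; exact adjusted p = 0.521).

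No pair of arrays held identical values. Tumours 2 and 3 were most alike, with a Pearson correlation of 0.806 across 1-Mb bins and the same call in 95.2% of bins, followed by tumours 1 and 5 at 0.726 and tumours 5 and 6 at 0.7105. These correlations are across bins, which are not independent replicates.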

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

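The 3 tests of the deep losses in this part were chosen only after the result was seen.

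A result stands apart here where 1 tumour lies far from the other 7, that is, where its gap to the nearest of them takes up more of the whole range than Dixon's test allows. Of 111 results tested in this way 16 stood apart, 6 of 21 chromosome means, 10 of 80 named genes, 0 of 5 measures per tumour and 0 of 5 antigen receptor loci. Chance flags about 1 in 20 groups, and genes on a chromosome share its losses.

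Chromosome 1 was at -0.50 in tumour 8, against -0.013 to 0.078 in the others. Chromosome 9 was at -0.11 in tumour 6, against 0.0043 to 0.046, and chromosome 19 at -0.22 in the same tumour, against -0.0076 to 0.069. Chromosome 18 was at -0.22 in tumour 2, against -0.015 to 0.067. Chromosome 11 was at 0.19 in tumour 4, against 0.011 to 0.082, and 2 genes on it, Nf2 and Egfr, were at 0.34 and 0.32 in that tumour, against 0.041 to 0.17 and 0.020 to 0.13. Steap3, on chromosome 1, was at -0.55 in tumour 8, against -0.25 to -0.041, while Tcea1, near the start of the same chromosome, was at 0.59, against -0.012 to 0.20. Skint6 was at 0.79 in tumour 8, against 0.24 to 0.47. Cdkn2a was at -2.60 in tumour 4, against -1.003 to -0.049, and Frmpd4 at -1.996 in tumour 1, against -0.56 to 0.078. Chromosome Y was at -1.45 in tumour 8, against -0.59 to 0.13, with Uty at -1.64, against -0.60 to 0.15, and Usp9y at -1.47, against -0.60 to 0.15.

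The deep losses at Cdkn2a, in Fhit, at the end of chromosome X and on chromosome Y could be loss of every copy in tumour cells, deletions that the animals carried in all their cells, or an effect of dim probes. If every copy was lost in the cells that carry a tumour's autosomal losses, the level of those losses predicts the depth, and the 7 deep losses lay 0.144 from that prediction on average (largest gap 0.449). They were picked by depth, however, and chromosome Y, lost less deeply in tumours 2 and 5, lay 0.795 from it on average, so this explanation stays open. With mode centring chromosome Y was at -0.40 in tumour 2 and -0.64 in tumour 5, against predictions of -1.54 and -1.09. With the same centring Cdkn2a in tumour 4 and Fhit in tumour 1 had deep losses at -2.51 and -2.10. Those tumours' autosomal losses were at -0.76 and -0.71, so these 2 places were lower than the other losses of the same tumour. The levels at the end of chromosome X ranged over 0.885 on the log2 scale, but tumour 1 is on another slide than tumours 5 and 7, which differed by 0.124. The losses began at 163399461, 164449267 and 164993844 in tumours 1, 5 and 7, which argues against 1 deletion shared by the animals. In male mice, with 1 chromosome X, a deletion in all cells would leave no DNA there. The level that an array gives for absent DNA was not measured. Lower levels did occur on the same slides, -2.50 at Cdkn2a in tumour 4 and -1.56 on chromosome Y in tumour 8. Those levels go against deletions in all cells but come from other arrays and other probes, so separate deletions carried in all cells stay open. Only 0.884% of the probes of these segments were dim, which speaks against dim probes.

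The short gained segments that recur at the same places, such as the segment with Skint6, may be extra copies of DNA or may come from probes with little signal in A/J DNA that read too high in the tumour channel. Dim probes outside every gained segment lay 0.43 ± 0.13 above their surroundings (SD, n = 8; exact sign-flip p = 0.0078125), which such probes would produce. They were picked, however, by the normal kidney signal of these same arrays, the denominator of the ratio. That choice raises their ratio in part by construction. In gained segments of mostly dim probes the brighter probes averaged 0.037 ± 0.044 (SE, 93 values of a probe in a tumour), against 0.80 for the dim ones (904 such values), which speaks against extra copies at the level of the dim probes. The same probe can count in several tumours, so these values are not independent, although the SE treats them so. The brighter probes were not set against the surrounding DNA, which is lost around some of these segments, so smaller gains are not excluded. Why dim probes read high was not tested.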

How the results depend on the processing

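Leaving out dim probes, mode centring together with the test against 0.1, the slide as a random block and the comparison with random lists were chosen only after the data were seen. No paired analysis was possible because the 8 tumours form 1 group. The results were recomputed under 1 changed choice at a time, except where 2 are named together, and of 254 recomputed values 191 stayed in the same direction and on the same side of the threshold, or within 1.5 times for counts. Results that leave out 1 tumour are given as ranges. Among the single genes named in the text, 947 recomputed values did not change their call, 245 were no longer past the threshold, 15 came to pass it and 14 changed sign. With 1 tumour left out these numbers were 533, 79, 9 and 3. Slide as a fixed block gave 3508 higher and 2921 lower genes, and as a random block 2716 and 2032 (correlation within slides 0.0825), where 11 named genes were no longer past the threshold.

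The percent of the genome lost (10.1% to 14.4%) held in every setting. The percent gained minus percent lost ran from -12.9 to -10.1 in the settings with all tumours and was not computed within slides. The 31 lost bins at distal chromosome 4 held wherever bins stayed at 1 Mb and all tumours were used. Leaving out 1 tumour gave lost shares of 11.9% to 13.98%, 31 lost bins throughout and 1 to 2 gained bins past the family-wise threshold.

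The cause of the following changes was not tested unless one is given. With mode centring 0 chromosomes were higher and 0 lower. Chromosome 4 averaged -0.35 there (exact adjusted p = 0.0547, unadjusted exact p = 0.0078125 with either centring). Mode centring also gave 1733 higher and 4096 lower genes, and 1 gained bin passed. Together with the test against 0.1 it gave 223 higher and 1241 lower genes. That test alone gave 520 and 825, segment means 5719 and 1034, and genes with at least 3 probes 2170 and 1041, where 7816 genes were tested. Normexp gave 1945 and 1750 genes, a gained share of 0.0242%, a most frequent gain in 1 tumour (permutation p = 1, n = 8) and 0 gained bins. The same 1 tumour and 0 bins came from probes well above background, with a gained share of 0.0395%, and from leaving out dim probes, with 0.0258%, 9 gained segments and 0 high-level gains.

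A call threshold of 0.15 gave a gained share of 0.985%, 1 whole-chromosome gain and 1 gained bin, and a threshold of 0.4 gave 1 gained bin. A penalty factor of 2 gave 180 lost and 284 gained segments and 4 gained bins, and a factor of 6 gave 70 and 55 segments. At least 3 probes per segment gave 238 gained and 77 high-level gained segments, at least 10 probes 71 gained segments and 1 gained bin, and bin medians without segmentation 20 gained stretches and 1 gained bin. A high-level limit of 0.7 gave 71 high-level gains and 11 deep losses, as its construction implies. With 0.5-Mb bins 60 lost and 4 gained bins passed, since there are more bins. With 4 tumours each, slide 1 gave 65 lost bins and 1 gained bin, while slide 2 gave 0 lost bins (most frequent loss in 3 tumours, permutation p = 0.742) and 0 higher and 0 lower genes. The 33 losses among renal carcinoma genes did not pass against random lists (adjusted permutation p = 0.537).

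Set against their flanks, the antigen receptor loci changed sign, Igh to 0.22, Igk to -0.013, Tcra/Tcrd to 0.092, Tcrb to -0.010 and Tcrg to 0.049, and without dim probes, also chosen after the data were seen, to 0.075, -0.014, 0.018, -0.010 and 0.049. Single genes changed sign with normexp (Prdx1 0.026, Akt1 0.15), with probes well above background (Skint5 -0.050), with segment means (Lcn2 -0.018, Brca2 -0.015, Fancd2 0.014, Ccnd2 0.014, Tfam 0.035, Slc11a2 -0.014, Tfeb 0.0021), within slide 1 (Skint5 -0.034, and a Trim12c mean log2 ratio of -0.085) and within slide 2 (Ptprd 0.088, Akt2 0.067). Leaving out 1 tumour gave -0.093 to 0.0087 for Prkd1 and -0.0060 to 0.079 for Trim12c. Signal over background noise was 208 to 263 in the normal kidney channel and 69.6 to 204 in the tumour channel, lowest in tumour 8. Most probes were dim in 92 of the 149 gained segments.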

Other observations

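The comparison with sign patterns and the test of neighbouring probes against a gene's own level were chosen only after the result was seen, and the genes named in this paragraph and the next were chosen after their values were seen. With dim probes left out, 9 gained segments were found, each in 1 tumour. Tumour 4 had a gain on chromosome 16 from 18186194 to 18560545, at 0.64 ± 0.041 (SE, 40 probes), with Txnrd2, the mitochondrial thioredoxin reductase, Dgcr8, which acts in microRNA processing, and Ranbp1. Tumour 5 had one on chromosome 17 from 30586287 to 31049473, at 0.39 ± 0.020 (SE, 50 probes), with Glo1, which detoxifies methylglyoxal, Glp1r, Btbd9 and Dnah8. Tumour 8 had 2 on chromosome 6, from 71375841 to 71774944 at 0.79 ± 0.032 (SE, 36 probes), with the histone demethylase Kdm3a, Reep1 and Chmp3, and from 72167629 to 72483097 at 0.85 ± 0.062 (SE, 31 probes), with Atoh8, Sftpb and Ggcx. The same tumour was gained on chromosome 1 from 3017293 to 6006459, at 0.49 ± 0.015 (SE, 171 probes), and lost on the rest of that chromosome from 6038742, at -0.52. The other 4, all in tumour 6, had 5 probes each, at 0.56 ± 0.45, 0.49 ± 0.49, 0.73 ± 0.45 and 0.67 ± 0.59 (SE, 5 probes each).

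The autosomes and chromosome X held 45 blocks of loss over 1 Mb, with a median length of 42.0 Mb, of which 36 reached a chromosome end and 9 did not. On chromosome 4 the loss in tumours 1, 4 and 8 counts as 2 blocks because gained segments in the Skint cluster, mostly of dim probes, interrupt it, and 2 of the 9 arise in this way. Chromosome 7 had a lost block in tumours 2, 3 and 7, at -0.54, -0.59 and -0.49. Chromosome 17 was lost towards its distal end in tumours 3 and 7, from 82115264 at -0.62 beginning at Slc8a1 and from 75576593 at -0.44 beginning at Ltbp1. Chromosome 5 had internal losses in tumours 7 and 8, at -0.43 and -0.54. Chromosome Y averaged -0.59 in tumour 5 and -0.37 in tumour 2. Among 15 pairs of recurrent losses, the pairs of chromosomes 7 and 13 (never in the same tumour) and of 13 and 14 (together in tumours 1, 5, 6 and 8) had the smallest Fisher exact p, 0.143 each (adjusted exact p = 0.737).

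The 4362 genes past the limma threshold that were called gained or lost in no tumour may reflect offsets of single probes that recur on every array, shifts of copy number over the surrounding DNA, or the GC content of the probes. Of 100 sign patterns of the 8 arrays 1, the measured one, called as many genes, 6051 in all against at most 809 in the others, which leaves little room for chance in that whole set. The 6051 include genes in called segments, and the 4362 were not counted apart. A copy-number shift inside the call limit, where the mean of 84.8% of these genes lies, would move the neighbouring probes as much as the gene. The 10 nearest probes lay at 17.9% ± 0.596 of the gene's level (SE over genes, which share arrays and segments). The genes were picked for passing the threshold and the neighbouring probes were not, which lowers this share whatever the cause. This comparison therefore does not decide on such shifts. After a loess on GC content 92.2% of them passed in the same direction, which speaks against GC content. Offsets of single probes stay open, since the correlation of 0.255 with the neighbouring probes could be low because called segments were left out and no array has swapped dyes.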
